A study of Mus musculus with 24 samples.

How the data were processed

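The series holds 24 arrays of cerebral cortex from male FVB mice at postnatal day 7, with 6 arrays each of WT polyribosomal, Fmr1 KO polyribosomal, WT total and Fmr1 KO total RNA. Per the labels' protocols, the cortices of 2 mice were pooled for each gradient, and a lysate was cleared by centrifugation, the last spin at 20000 g. Of this lysate 20% was set aside as total RNA, and the rest was spun through a 20% to 50% sucrose gradient. The gradient was collected in 16 fractions, and fractions 10 to 13, with mRNAs on 6 or more ribosomes, were pooled as polyribosomal RNA. Labelled cRNA (10 µg) was put on Affymetrix Mouse 430 2.0 arrays. The 6 replicates of a genotype were thus 6 pools of mice. The study was set up with 6 pairs of WT and Fmr1 KO littermates.

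Per the submitters' processing notes, the values were made with GCRMA, which corrects the background, normalizes between arrays and summarizes each probe set. The deposited values are on the log2 scale, which was judged from their range and nearly equal medians. The version of GCRMA, and whether all 24 arrays were normalized together, were not stated. The quantiles of the 24 arrays nearly coincide. No scan dates or batches were given, and no 2 arrays were identical. The number of arrays limits the precision. Gene positions are given by chromosome only, and gene order on the X chromosome was taken from the GRCm38.p6 RefSeq annotation.

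The platform annotation gave 1 gene symbol for 34945 of 45037 probe sets, several for 932 and none for 9160, with 18193 distinct symbols. Of the 1-symbol probe sets, 34741 had a gene ID in the RefSeq table. Probe sets with no or several symbols were tested and counted, but not named. A probe set was tested when its log2 value was at least 4 in at least 6 of the arrays compared.

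Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. There were 5 comparisons: Fmr1 KO against WT in polyribosomal RNA, the same in total RNA, polyribosomal against total RNA in WT and in Fmr1 KO with the lysate as a block, and the polyribosomal minus total differences of the 12 lysates between genotypes. The last one tests the interaction of genotype and RNA kind. Counts of genes, and values of a gene where no probe set is named, use 1 probe set per gene, the one with the highest mean over the 24 arrays. Fmr1 was compared with a two-sided exact permutation test. A p of a single gene in the text is a limma adjusted p unless named otherwise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

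Whether equal replicate numbers mark matched samples was checked from the residuals after removing group means. Residuals of WT and Fmr1 KO arrays of one number correlated at 0.133 to 0.532 in total RNA and at -0.14 to 0.625 in polyribosomal RNA. Those of polyribosomal and total arrays of one number correlated at 0.021 to 0.525 in WT and 0.156 to 0.474 in Fmr1 KO. Among total arrays, that of its own number was the best match of a polyribosomal array for 5 of 6 in WT and 6 of 6 in Fmr1 KO. Most WT total arrays, however, matched a WT polyribosomal array of another number best. Among Fmr1 KO arrays, the own number was the best match of a WT array for 4 of 6 in total and 3 of 6 in polyribosomal RNA. The replicate number was used as a block for the genotype comparisons only as an alternative, because the labels do not say that it marks the littermate pair.

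Gene lists, 31 in number with 1222 entries, of which 1218 matched a symbol, were written from general knowledge before the data were examined. They covered FMRP-bound mRNAs, the FMRP family and partners, presynaptic vesicles, the postsynaptic density, GABA receptors and synthesis, ribosomal proteins, translation factors, oxidative phosphorylation, the mTOR and PI3K pathway, chromatin regulators, ubiquitin ligases, motor and cytoskeleton genes, the proteasome, chaperones, the integrated stress response, immediate early genes, cholesterol synthesis, long noncoding RNAs, replication histones, the cell cycle, radial glia and progenitors, X-linked genes near Fmr1, and markers of excitatory neurons, interneurons, astrocytes, the oligodendrocyte lineage, microglia, endothelium and pericytes, meninges and choroid plexus, blood and other brain regions. The FMRP-bound list was written from memory of published FMRP-bound brain mRNAs. Lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists of a comparison, and also with an estimated correlation, with fry, and with an exact permutation of the mean of the list. For the genotype comparisons the list means were also compared by replicate number with an exact sign-flip test.

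Genes named in the text were chosen by a rule fixed before the data were examined. In each comparison these were the 10 largest rises and the 10 largest falls among genes past the threshold with the same direction in all 6 same-numbered pairs or lysates. Where fewer than 5 genes passed, they were the 5 genes with the smallest p. To these came the 3 largest changes past the threshold of each list described, or its largest value where none passed, and Fmr1. Exceptions are named where they occur.

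Alternatives tried were a replicate block or none, all 24 arrays in one fit, no dim-probe filter or a limit of 6, quantile normalization, median centring, 1 probe set per gene, an intensity trend with a robust prior, array weights, a minimum log2 change of 0.5, and leaving out each replicate number. For the lists, the mean of a gene's probe sets was also tried. The pipeline was tested on simulated data of the same size and spread, with 200 changed probe sets and independent noise. A log2 change of 1 was recovered in 87.5% to 98.5% of them over the 5 comparisons. These shares do not hold for a lone change, since the adjustment is stricter when fewer probe sets change. No array was left out of the comparisons.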

Results

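RNA levels were measured on 24 Affymetrix Mouse 430 2.0 arrays, which hold probe sets for most mouse mRNAs. The tissue was cerebral cortex of male FVB mice at postnatal day 7, either wild type (WT) or lacking Fmr1 (Fmr1 KO), the gene of the RNA-binding protein FMRP that is silenced in fragile X syndrome. Each genotype had 6 cortical lysates, each a pool of 2 mice. Each lysate gave 1 polyribosomal and 1 total RNA array, so each of the 4 groups held 6 arrays. Polyribosomal RNA came from the gradient fractions with mRNAs carrying 6 or more ribosomes. Total RNA came from the part of the lysate set aside before the gradient. The median log2 value of an array lay near 3.18, and 38.8% to 40.0% of the 45037 probe sets of an array reached a log2 value of 4. Across probe sets, Pearson's r between arrays of a group was 0.991 to 0.997 in polyribosomal RNA and 0.995 to 0.998 in total RNA. That between a polyribosomal and a total array was 0.980 to 0.988. The number of arrays limited the precision. The median 95% half-width of a log2 difference between genotypes was 0.291 in polyribosomal and 0.182 in total RNA.

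Fmr1 was lower in every Fmr1 KO array than in every WT array of the same RNA kind, at each of its 3 probe sets. In polyribosomal RNA its brightest probe set stood at a log2 value of 9.90 ± 0.21 (SD, n = 6) in WT and 6.19 ± 0.48 (SD, n = 6) in Fmr1 KO, a 13.1-fold difference. In total RNA it stood at 9.66 ± 0.18 (SD, n = 6) and 6.38 ± 0.16 (SD, n = 6), a 9.69-fold difference. The second probe set stood at 7.14 ± 0.39 (SD, n = 6) in WT and 3.97 ± 0.29 (SD, n = 6) in Fmr1 KO polyribosomal RNA, and was 4.74-fold lower in Fmr1 KO total RNA. The dimmest stood at 5.05 in WT and 3.85 in Fmr1 KO polyribosomal RNA, and at 4.65 and 3.62 in total RNA. The two-sided exact permutation p was 0.00216 for each probe set in each RNA kind, the smallest that the 924 splits of 6 against 6 arrays allow. The brightest probe set still gave a signal above the dim-probe limit of 4 in all Fmr1 KO arrays, while the Fmr1 KO means of the dimmest in both RNA kinds and of the second in polyribosomal RNA lay below it. For these no fold difference is given.

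**Figure D1:**
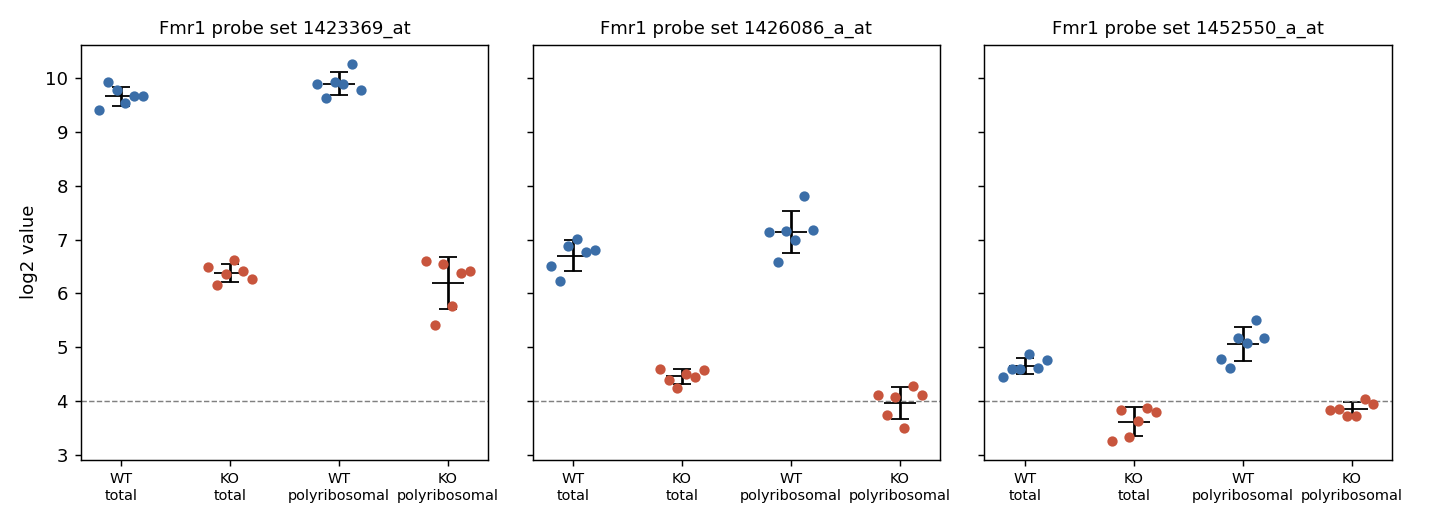
The log2 values of the 3 Fmr1 probe sets are plotted for each array, by genotype and RNA kind, with the mean and SD of 6 arrays as bars and the dim-probe limit of 4 as a dashed line. All Fmr1 KO arrays lie below all WT arrays of the same RNA kind, by 3.71 log2 units on average for the brightest probe set in polyribosomal RNA.

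FMRP binds many neuronal mRNAs and associates with polyribosomes, and the first comparison asked which mRNAs differ in polyribosomal RNA when it is missing. Fmr1 was the only gene past the threshold in polyribosomal RNA, where each of its 3 probe sets was lower (limma adjusted p = 4.35e-08, 8.76e-08 and 0.00109), the brightest by 3.71 on the log2 scale. Among the other genes, the smallest p values belonged to Haus7, a subunit of the augmin complex of the mitotic spindle, at -0.95 (SE 0.17, adjusted p = 0.270, lower in 6 of 6 same-numbered pairs). Nsun3 at 0.57, E130307A14Rik at 0.40 and Tnrc6c at -0.40 followed, and none of the 4 passed. The list of FMRP-bound mRNAs had no called member among 144 measured, over all genes or adjusted over the list alone. Unadjusted, 2 members, both with lower values, had a p under 0.05. Of its members, 109 had values below 0 and 35 above. The largest value was that of the postsynaptic scaffold gene Dlgap2, at -0.39 (SE 0.17).

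Small downward values ran through several lists in Fmr1 KO polyribosomal RNA. With camera's preset correlation, 6 of 29 lists were lower. They were FMRP-bound mRNAs (median -0.08, adjusted p = 6.51e-06), motor and cytoskeleton genes (median -0.08, adjusted p = 6.51e-06) and the FMRP family and partners, which includes Fmr1 (median -0.06, adjusted p = 0.000594). The others were GABA receptors and synthesis (median -0.10, adjusted p = 0.00954), astrocyte markers (median -0.11, adjusted p = 0.00954) and ubiquitin ligases (median -0.06, adjusted p = 0.0293). None of these 6 calls held with camera's estimated correlation, where each list had an adjusted p = 0.766 with an estimated correlation, nor with fry. The members with the largest values, none of which passed, were Plec at -0.34 among 57 motor and cytoskeleton genes, Gabrd at -0.40 among 17 GABA genes, Aldh1l1 at -0.26 among 21 astrocyte markers and Ube3b at -0.25 among 37 ubiquitin ligases. No list was higher. Ribosomal protein mRNAs (41 measured, median 0.03) and proteasome mRNAs (32 measured, median 0.05) had camera adjusted p = 0.129 each. Without the number 5 lysates 1 list was called, and the FMRP-bound list then had an adjusted p = 0.344. The mean of the FMRP-bound list relative to all genes was 1.54 ± 0.17 (SD, n = 6) in WT and 1.46 ± 0.19 (SD, n = 6) in Fmr1 KO polyribosomal RNA, a difference smaller than the spread between arrays.

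**Figure D2:**
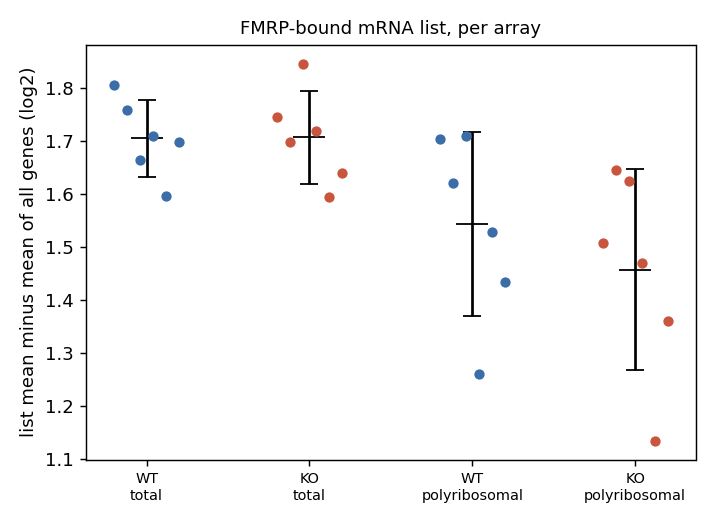
Each point is 1 array, and the vertical axis gives the mean log2 value of the 144 measured FMRP-bound mRNAs minus the mean of the 9956 genes measured, with the mean and SD of 6 arrays as bars. The WT and Fmr1 KO arrays overlap in both RNA kinds, and the polyribosomal arrays spread more widely (SD 0.17 and 0.19) than the total arrays (SD 0.073 and 0.088).

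Of the 17687 probe sets tested in polyribosomal RNA, limma called 3 lower and 0 higher in Fmr1 KO. An unadjusted p under 0.05 was reached by 473 probe sets, where chance alone gives about 884. With a count this far below chance, the p values were not spread evenly. The count therefore does not show that effects were absent. In simulated data of this size, each run had 200 probe sets changed by a single size. Of these, 37.5% were recovered at a change of 0.5 log2 units, 92% at 1 and 0% at 0.25. Changes under 0.5 would thus mostly have been missed. A lone change would be recovered less often, because the adjustment is stricter when fewer probe sets change. Haus7, at -0.95, did not pass here (limma adjusted p = 0.270).

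The second comparison asked which mRNAs differ in total lysate RNA of Fmr1 KO cortex, the level against which polyribosome association is judged. Besides Fmr1, which fell by 3.28 on the log2 scale at its brightest probe set (limma adjusted p = 1.29e-10), 4 genes passed at any of their probe sets. With 1 probe set per gene 3 of them passed, all but Lgals1. Haus7 fell by 0.98 (SE 0.11, adjusted p = 0.00250), a 1.97-fold difference. Maob, which encodes the amine-degrading enzyme monoamine oxidase B, fell by 0.50 (SE 0.067, adjusted p = 0.0105). Fundc2, a gene of a mitochondrial outer membrane protein, rose by 0.42 at its brighter probe set (SE 0.053, adjusted p = 0.00659). Its other probe set stood at -0.48 (adjusted p = 0.116), so the direction for Fundc2 depended on the probe set. Lgals1, which encodes galectin-1 and was chosen after its values were seen, fell by 0.41 at 1 probe set (SE 0.062, adjusted p = 0.0361). Its other probe set stood at -0.18 (adjusted p = 0.837). Each of the 4 moved the same way in 6 of 6 same-numbered pairs. Haus7, Maob and Fundc2 are on the X chromosome, as is Fmr1.

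In polyribosomal RNA the values of these genes were -0.95 for Haus7, -0.51 for Maob, 0.59 for Fundc2 at its brighter probe set and -0.12 for Lgals1, none past the threshold. The list of X-linked genes near Fmr1 had no called member among 23 measured over all genes. It had 5 members with an unadjusted p under 0.05, all with lower values, and 1 lower when adjusted over the list alone. Its member with the largest value was Slitrk2, a synaptic adhesion gene, at -0.41 (adjusted p = 0.837). Nsdhl, an enzyme of cholesterol synthesis, stood at -0.28 (adjusted p = 0.259, lower in 6 of 6 pairs). Of the cholesterol synthesis genes none of 22 passed over all genes and 1 passed, lower, adjusted over the list alone. Hebp1, a heme-binding protein gene, was among the 5 genes with the smallest p and stood at -0.40 (adjusted p = 0.177). None of the 144 FMRP-bound mRNAs passed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 had higher and 1 lower values, and the list's median was -0.01 (camera adjusted p = 0.963). Other members with the largest values in their lists, none past the threshold, were Gabrg1 at -0.32, the ubiquitin ligase gene Wwp1 at -0.34, the astrocyte marker Ntsr2 at -0.36 and the microglial marker Aif1 at -0.29. All 4 microglial markers measured, too few to be tested as a list, had values below 0, and 1 passed, lower, adjusted over the list alone. Of 4 replication histone genes, also too few, 1 passed, higher, adjusted over the list alone. The choroid plexus gene Ttr stood at -2.01 (SE 1.90) in total and -2.35 (SE 1.95) in polyribosomal RNA, values within its spread between lysates.

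Of 17850 probe sets tested in total RNA, limma called 1 higher and 6 lower. Of all tested, 892 had an unadjusted p under 0.05, as many as the 892.5 that chance gives. With camera's preset correlation 0 of 28 lists passed and 7 had an unadjusted p under 0.05. Fry called 1, the FMRP family and partners, which includes Fmr1 (adjusted p = 0.000603). With the replicate number as a littermate block, 4 probe sets passed, those of Fmr1 and Haus7, and Maob, Fundc2 and Lgals1 no longer did (adjusted p = 0.0699, 0.0852 and 0.155). Without any 1 replicate number Lgals1 did not pass (adjusted p = 0.0654 to 0.339). Without the number 1 or the number 4 lysates 2 probe sets passed, and Haus7 then had an adjusted p = 0.0513 and 0.0761. Maob passed when number 6 was left out but not for the others (adjusted p = 0.100 without number 4 to 0.149 without number 5). Fundc2 passed when number 5 was left out but not for the others (0.0522 without number 3 to 0.116 without number 2).

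The third comparison described which mRNAs of WT cortex were over- or under-represented in the polyribosomal pool relative to the lysate. Long noncoding RNAs and mRNAs of ribosomal proteins were depleted from this pool, and mRNAs of the proteasome and of the cell cycle were enriched. The pool was taken from the fractions with mRNAs on 6 or more ribosomes only. A fall therefore does not show that an mRNA was off polyribosomes or poorly translated. All 15 long noncoding RNAs measured were lower in polyribosomal RNA, with a list median of -1.95, among them the small nucleolar RNA host genes Snhg8 at -4.29 (SE 0.17), Gas5 at -3.48 (SE 0.17) and Snhg1 at -3.07 (SE 0.15). Of 41 ribosomal protein mRNAs, 35 were lower, 6 did not pass and none was higher, with Rpl41 at -2.57, Rps15 at -1.90, Rps26 at -1.86 and a median of -0.72. In contrast, 28 of 32 proteasome mRNAs were higher and none was lower, with Psmd13 at 0.91, Psmd3 and Psmd7 at 0.90 each and a median of 0.55. Likewise 17 of 20 cell cycle mRNAs were higher and none was lower, with Cdca8 at 1.33, Ccnd2 at 1.09, Mcm5 at 1.07 and a median of 0.67.

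**Figure D3:**
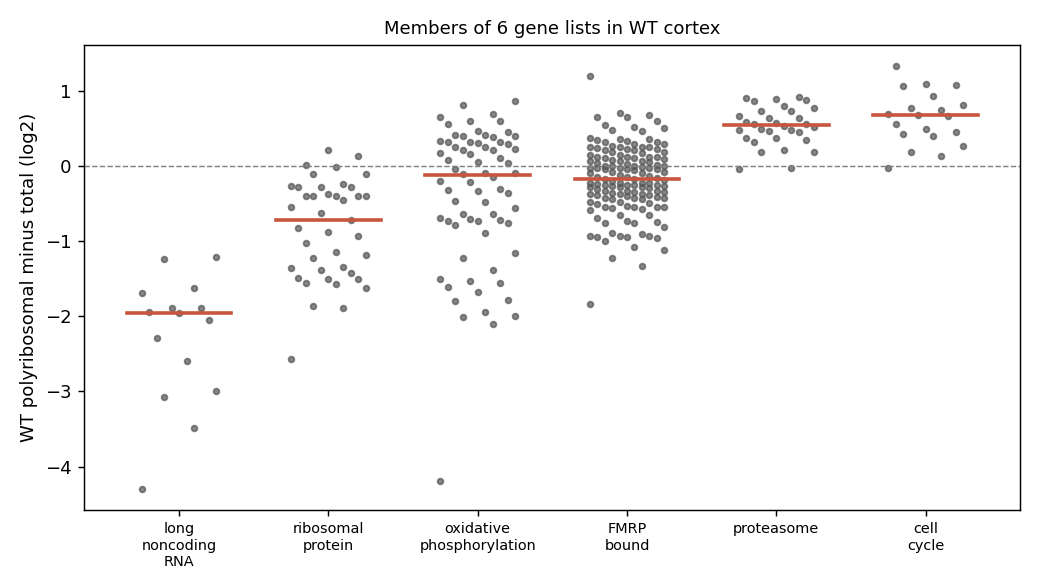
The polyribosomal minus total log2 difference in WT cortex (mean of 6 lysates) is plotted for each measured member of 6 gene lists, with the list median as a red line and 0 as a dashed line. All 15 long noncoding RNAs lie below 0, with a median of -1.95, and the proteasome list has a median of 0.55.

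The adjusted p of these lists under camera's preset correlation was 1.31e-10 for long noncoding RNAs and for ribosomal proteins, 3.02e-06 for the proteasome and 0.000128 for the cell cycle. All 4 calls were lost with an estimated correlation, where each had an adjusted p = 0.380 with an estimated correlation. Fry called all 4 (adjusted p = 7.47e-05 for long noncoding RNAs and 8.85e-05 for the others), but it tests a list alone and called 17 of the 28 lists in WT. Oxidative phosphorylation was split, with 23 of 70 mRNAs higher and 31 lower (median -0.13, adjusted p = 0.0401, and adjusted p = 0.798 with an estimated correlation). Its lower members included Atp5e, a subunit of ATP synthase, at -4.19, the complex I gene Ndufa3 at -2.10 and the complex III gene Uqcr11 at -2.01. FMRP-bound mRNAs leaned towards depletion, with 63 of 144 lower, 27 higher and 54 not past the threshold (median -0.17, adjusted p = 0.0197, and adjusted p = 0.798 with an estimated correlation). The lowest were the presynaptic scaffold gene Pclo at -1.84, the ankyrin gene Ank3 at -1.33 and the dynein heavy chain gene Dync1h1 at -1.22. Without the number 4 lysate, whose polyribosomal array stood apart from the others of its kind, the FMRP-bound list had an adjusted p = 0.0754.

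Among single genes, the largest fall was that of ND5, a mitochondrially encoded subunit of complex I, at -4.93 (SE 0.18, adjusted p = 8.04e-09). It was followed by the ubiquitin ligase gene Marchf2 at -4.41, Snhg8, Atp5e and the mitochondrial import gene Timm8b at -3.53. Next came A530058N18Rik at -3.49, Gas5, the selenoprotein gene Selenow at -3.40, the G protein subunit gene Gng13 at -3.24 and Tmem256 at -3.14. The largest rise was that of Fxr2, an autosomal relative of Fmr1, at 2.64 (SE 0.17, adjusted p = 2.95e-07), from 1 probe set. The other relative Fxr1 stood at -0.49 (adjusted p = 0.000652), a gene chosen after its values were seen. Eepd1 at 2.36, Tspyl5 at 1.75, Rps4l at 1.72, Gm5124 at 1.54, Cryl1 at 1.52, and the endocytosis gene Pacsin1 at 1.51 followed. The mitochondrial ribosome gene Mrpl19, Eipr1 and the Mediator subunit gene Med16 completed the 10, the last at 1.48. The 10 falls and 10 rises moved the same way in 6 of 6 lysates, which the rule for naming them required. The probe sets named here for Marchf2, Atp5e, Gas5, Selenow and Rpl41 are of the _x_at or _s_at kind, which can also bind related transcripts.

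The other lists of synaptic and regulatory genes held called members on both sides in WT cortex, and camera called none of those it tested. Presynaptic vesicle genes had 11 higher and 7 lower of 37. Postsynaptic density genes had 6 higher and 15 lower of 37 with Cacng2 at -1.52. GABA genes had 2 higher and 9 lower of 18 with Gabra2 at -1.67 and the vesicular transporter gene Slc32a1 at 0.67. Translation factors had 13 higher and 14 lower of 46 with the poly(A)-binding protein gene Pabpc1 at -1.84. The mTOR and PI3K pathway had 12 higher and 9 lower of 28 with Ddit4 at 1.32 and Rps6 at -1.43. Chromatin regulators had 17 higher and 20 lower of 52 with Atrx at -1.47. Ubiquitin ligases had 9 higher and 15 lower of 37 with Wwp1 at -1.70, and motor and cytoskeleton genes 13 higher and 22 lower of 57 with Dst at -1.82. Chaperones had 10 higher and 6 lower of 30 with Cryab at -1.52. The integrated stress response had 14 higher and 6 lower of 22 with the serine synthesis enzyme gene Phgdh at 1.00. Immediate early genes had 14 higher and 3 lower of 24 with Junb at 1.31 and Gadd45g at 1.19 (camera adjusted p = 0.0708). Cholesterol synthesis genes had 9 higher and 3 lower of 22 with Pmvk at 1.21 and Tm7sf2 at -1.81, and replication histone genes 2 higher and 1 lower of 4, too few to be tested as a list. The FMRP family and partners had 10 higher and 5 lower of 24. The X-linked genes near Fmr1 had 11 higher and 6 lower of 24 with Mtm1 at -1.29.

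Most lists of cell type markers held called members on both sides in WT cortex, and camera called none of those it tested. Astrocyte markers had 10 higher and 3 lower of 21 with Mlc1 at 1.32 and Fgfr3 at 1.13. Interneuron markers had 7 higher and 4 lower of 17 with Calb2 at 1.23 and Reln at -0.87, and excitatory neuron markers 4 higher and 5 lower of 20 with Foxp2 at -1.55 and Crym at 0.77. Oligodendrocyte lineage markers had 5 higher and 2 lower of 12 with Olig2 at 0.88 and Tspan2 at -1.33. Radial glia and progenitor genes had 4 higher and 5 lower of 14 with Ptprz1 at -0.97, and microglial markers 2 higher and 1 lower of 4, too few to be tested as a list. Endothelial and pericyte markers had 3 higher and 0 lower of 7, meningeal and choroid plexus markers 5 higher and 2 lower of 8, and markers of other brain regions 6 higher and 0 lower of 11 with Ppp1r1b at 0.84. No blood marker was measured above the dim-probe limit. Adjusted over the list alone, the counts were the same or differed by at most 2 genes in each direction.

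Of the 17893 probe sets tested in WT, limma called 6483 higher and 5214 lower in polyribosomal RNA, with the lysate as a block. By gene, 3650 of 9726 were higher, 2761 were lower and 3315 did not pass, and 199 were higher and 776 lower by at least 2-fold. These are relative levels, since all arrays have nearly the same distribution of values, so they do not show how much of all mRNA was on polyribosomes.

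The fourth comparison repeated this in Fmr1 KO cortex, and the same groups stood out. All 15 long noncoding RNAs were lower (median -1.96), with Snhg8 at -4.27 and Gas5 at -3.30. Likewise 34 of 41 ribosomal protein mRNAs were lower and 1 was higher (median -0.71), with Rpl41 at -2.52. Of the proteasome mRNAs 29 of 32 were higher and none was lower (median 0.56), with Psmd7 at 1.02 and Psmb2 at 1.01. Of the cell cycle mRNAs 18 of 20 were higher and none was lower (median 0.64), with Cdca8 at 1.45, Hmgb2 at 1.39 and Ccnd2 at 1.27. FMRP-bound mRNAs had 72 of 144 lower and 19 higher (median -0.24), with Pclo at -2.06, Ank3 at -1.66 and Dync1h1 at -1.48. The largest changes were again those of ND5 at -5.20 (SE 0.28), Marchf2 at -4.38 and Snhg8 among falls and of Fxr2 at 2.45 (SE 0.13), Eepd1 at 2.38 and Rps4l at 1.93 among rises. Agpat1 at -3.25 and Uqcc2 at -3.19 were among the 10 largest falls, and Rpa2 at 1.75, Ech1 at 1.63 and Ccs, the copper chaperone of superoxide dismutase, at 1.60 were among the 10 largest rises.

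Under camera's preset correlation the adjusted p in Fmr1 KO was 5.10e-10 for long noncoding RNAs and ribosomal proteins, 7.24e-07 for the proteasome, 0.000156 for the cell cycle and 0.000223 for FMRP-bound mRNAs. These 5 calls were lost with an estimated correlation, with adjusted p = 0.401 for long noncoding RNAs and the proteasome, 0.540 for ribosomal proteins, 0.530 for the cell cycle and 0.762 for FMRP-bound mRNAs with an estimated correlation. Oxidative phosphorylation had 23 of 70 higher and 32 lower and did not pass (adjusted p = 0.0853). Of 17854 probe sets limma called 6633 higher and 5133 lower, and by gene 3752 of 9703 were higher, 2740 were lower and 3211 did not pass.

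The last comparison asked whether polyribosome association itself differed between the genotypes, from the polyribosomal minus total difference of each lysate. No gene passed. The association of genes in Fmr1 KO followed that in WT, with a Pearson's r of 0.979 and a Spearman's rho of 0.969 across 9956 genes. The slope of their first principal component, which is not a regression slope, was 1.00. Genes are not independent replicates. Of the 9648 genes tested in both genotypes, 3275 were higher and 2488 were lower in polyribosomal RNA in both. Of 10373 probe sets called in both genotypes, 10372 had the same direction. The remaining 1 was the second Fmr1 probe set, named after its values were seen, at 0.44 in WT (adjusted p = 0.00760) and -0.49 in Fmr1 KO (adjusted p = 0.00222). Its Fmr1 KO mean in polyribosomal RNA, 3.97, lay below the dim-probe limit of 4, so its direction in Fmr1 KO is uncertain. At the brightest Fmr1 probe set the difference in association was -0.43 (SE 0.20, adjusted p = 0.999). It was -0.93 (SE 0.17, adjusted p = 0.999) at the second and -0.17 (SE 0.15, adjusted p = 0.999) at the dimmest, both with Fmr1 KO values near the limit.

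**Figure D4:**
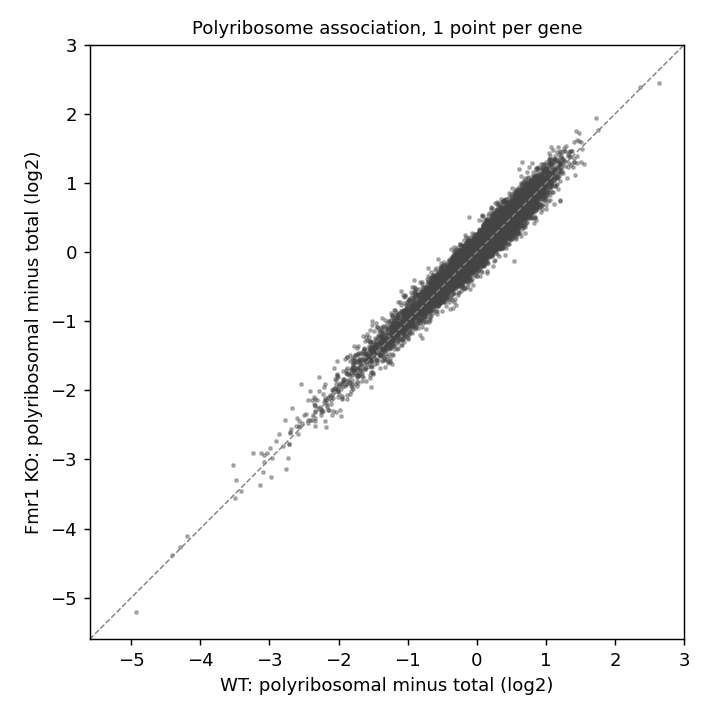
Each point is 1 of the genes measured, with its polyribosomal minus total log2 difference in WT (mean of 6 lysates) on the horizontal axis and in Fmr1 KO on the vertical axis, and the dashed line marks equal values. The points follow the line with a Pearson's r of 0.979, from ND5 at -4.93 and -5.20 to Fxr2 at 2.64 and 2.45.

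The genes with the smallest p for this difference were Cmbl at 0.65, the kinetochore gene Cenph at 0.60, the DNA damage checkpoint gene Rad1 at 0.47, Lsm6 at 0.43 and the kinase gene Nek8 at -0.38, each with an adjusted p = 0.999. Of the FMRP-bound mRNAs, 104 of 144 had values below 0 and 40 above. An unadjusted p under 0.05 was reached by 2 of them, both with lower values, and none passed over all genes or adjusted over the list alone. Their largest value was that of Adgrb2, an adhesion receptor gene, at -0.35 (SE 0.16). With camera's preset correlation 3 of 29 lists were lower in Fmr1 KO. They were FMRP-bound mRNAs (median -0.07, adjusted p = 4.29e-06), motor and cytoskeleton genes (median -0.09, adjusted p = 4.29e-06), with Ank3 at -0.33, and chromatin regulators (median -0.03, adjusted p = 0.0408), with Chd1 at -0.45. None of the 3 calls held with an estimated correlation, where each had an adjusted p = 0.791 with an estimated correlation, nor with fry. Without the number 5 lysates the FMRP-bound and motor lists had adjusted p = 0.363 and 0.0832.

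Limma called 0 of 18544 probe sets in this comparison, and the limma fit to 24 arrays without the lysate term also called 0. An unadjusted p under 0.05 was reached by 442, where chance gives about 927. As in polyribosomal RNA, this low count does not show that effects were absent. The median 95% half-width was 0.313 log2 units. In simulated data with 200 changed probe sets, 21.5% of those changed by 0.5 log2 units and 87.5% of those changed by 1 were recovered. Smaller changes in association were thus mostly not detectable with 6 lysates per genotype. A lone change, even of this larger size, would be missed more often than in the simulation. The second Fmr1 probe set, at -0.93, did not pass (limma adjusted p = 0.999).

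The differences between genotypes in total and polyribosomal RNA, which come from the same lysates, correlated across 9956 genes with a Pearson's r of 0.382 and a Spearman's rho of 0.254, where genes are not independent replicates. With Fmr1 left out the Pearson's r was 0.321. Haus7, at -0.98 in total and -0.95 in polyribosomal RNA, and Maob, at -0.50 and -0.51, were close in both RNA kinds, and their differences in association were 0.03 and -0.01 (adjusted p = 0.999 each). Of 100 splits of the 12 lysates into 6 and 6, the real one included, 28 gave a correlation at least as high.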

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

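The tests of probe variants, chance placement on the X chromosome, with or without Lgals1, shared variation of the FMRP-bound list, the arrays that stood apart, together, alone or by number, and their swap, and the splits for counts of genes in polyribosomal RNA, in association and with Fmr1 left out, and all splits that part the same-numbered pairs, were chosen after the result was seen; the other tests in this part were set before.

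Besides Fmr1, the genes called in total RNA with 1 probe set per gene (Haus7, Maob and Fundc2) were all X-linked, while Lgals1, called at its dimmer probe set, is on chromosome 15. Chance placement was argued against, since 3 of 3 such genes were X-linked against 330 of 9664 tested (one-sided Fisher's exact p = 3.95e-05), and 3 of 4 with Lgals1 (p = 0.000154), though with the replicate block only Haus7 still passed, and Maob, Fundc2 and Lgals1 did not (adjusted p = 0.0699, 0.0852 and 0.155). The X chromosome was singled out after the calls. Multiplied by the 23 chromosome labels, the Fisher's exact p was 0.000908, and 0.00354 with Lgals1. A segment carried along with the null allele stays open, because its test cannot decide. A share of 0.0424 of the 330 windows of 100 X-linked genes had as high a mean absolute t as the window around Fmr1. That window held 2 of the 3 called genes, and the share was 0.0545 with the called genes left out. Neighbouring windows share nearly all of their genes, so neither share measures chance. In the list of X-linked genes near Fmr1, 5 of 23 members had an unadjusted limma p under 0.05 in total RNA, all lower. Camera did not call that list (adjusted p = 0.168). A sequence variant under the probes may account for Fundc2, whose probe sets lay 0.896 apart (SE 0.0986) on the log2 scale in opposite directions. An effect of FMRP loss on the level of these mRNAs stays open and was not tested apart from these.

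FMRP-bound mRNAs were lower as a list in Fmr1 KO polyribosomal RNA under camera's preset correlation. Without both arrays that stood apart the difference in the list mean was -0.0783 (exact permutation p = 0.325), against -0.0864 with all arrays, but the 2 arrays offset each other. The KO number 5 array alone may account for much of the difference, which was -0.0222 without it (exact permutation p = 0.829), -0.0249 without both number 5 polyribosomal arrays (0.833), and -0.142 without the WT number 4 array (0.182), and without the number 5 lysates the list was not called (adjusted p = 0.344). Variation between polyribosomal arrays that the members share may account for the call, since the exact permutation p of the list mean over all 924 splits was 0.437. An effect of FMRP loss of this small size stays open, since a p that misses the threshold does not exclude it.

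The polyribosomal arrays of WT number 4 and KO number 5 stood apart from the other 10, at 38.8 and 39.3 on the first principal component against -17.6 to 4.80. A swap between genotypes was argued against, since Fmr1 was 3.50 log2 units higher in the WT array. A different tissue composition was argued against for WT number 4 only. Along the same axis its matched total array lay at 0.518, within the -4.98 to 3.99 of the other 10 lysates. The matched total array of KO number 5 lay at 7.33, above that range, so a different composition stays open for this lysate. A difference in the gradient or in the preparation of these polyribosomal samples could not be tested, and no other biological explanation was tested.

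Single values lay far from the other 5 of their group in 4 of 106 sets of 6 values, where chance gives about 1 in 20 groups, or 5.3. In WT polyribosomal RNA, Nsdhl stood at 9.04 in number 4 against 9.49 to 9.76 in the others. In WT total RNA, Dlgap2 stood at 4.52 in number 1 against 3.99 to 4.15. The polyribosomal minus total difference of Gas5 was -4.59 in WT number 3 against -3.43 to -3.11, and -4.11 in KO number 3 against -3.27 to -3.03.

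For 3 lists, polyribosome association was lower in Fmr1 KO than in WT by camera's test of the difference at its preset correlation, with medians of -0.0724 for FMRP-bound mRNAs, -0.0341 for chromatin regulators and -0.0920 for motor and cytoskeleton genes. Each was lost with an estimated correlation (adjusted p = 0.791 with an estimated correlation).

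Other splits of the 12 lysates were counted, 100 drawn of 462 with the real one included. For genes in polyribosomal RNA, 3 of 100 splits gave as many calls as the real 3 (highest other 109), and in total RNA 4 of 100 gave as many as the real 7 (highest other 714), but all 3 and 3 of the 7 were probe sets of Fmr1. With Fmr1 left out, 6 of 100 gave as many as the real 4 in total RNA (highest other 714), so chance was not excluded for the other genes there. In polyribosomal RNA the count was then 0, which 100 of 100 splits reach (highest other 109), so it says nothing about chance. The 109 and the 714 calls came from the same split. A structure of the samples other than genotype may account for them, which was not tested. For the difference in association 100 of 100 splits gave at least the real 0 (highest other 26), as any split must, so this too says nothing. Chance was not excluded for the correlation of genotype differences, where 28 of 100 were as high as 0.382 (highest other 0.615), or 38 of 100 as high as 0.321 with Fmr1 left out (highest other 0.612).

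All 32 splits that part the 6 same-numbered pairs were also counted, although the labels do not say that the numbers mark littermates. With Fmr1 left out, 1 of 32, the real one, gave as many calls in total RNA as the real 4 (highest other 1). This is the lowest share that 32 splits allow. It argued against chance for this count among these splits, unlike among all splits. With the replicate block, which rests on the same numbers, only Haus7 of these genes still passed. Chance was not excluded for the correlation, where 3 of 32 were as high as 0.382 (highest other 0.425), or 4 of 32 as high as 0.321 with Fmr1 left out (highest other 0.416). Nor was it for lists, where 20 of 32 gave as many as the real 6 in polyribosomal RNA (highest other 12) and 23 of 32 as many as the real 3 for association (highest other 12).

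In total RNA 100 of 100 splits gave at least the real 0 lists (highest other 13), which likewise says nothing. Chance was not excluded for the counts of lists in polyribosomal RNA and in association. In polyribosomal RNA 75 of 100 splits gave as many as the real 6 (highest other 16), and for association 84 of 100 as many as the real 3 (highest other 12). Among the 32 exchanges of polyribosomal and total RNA within lysates, 22 gave as many lists as the real 6 in WT (highest other 12) and 27 as many as the real 5 in Fmr1 KO (highest other 10). These counts cannot tell a shift of lists from chance. Most exchanges keep part of the difference between RNA kinds, by which camera ranks lists, even where no gene is called. For genes, 1 of 32 exchanges, the real one, gave as many calls as the 11697 in WT and the 11766 in Fmr1 KO. The highest other was 0 in each. Chance was thus argued against, at the lowest share that 32 exchanges allow.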

How the results depend on the processing

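Leaving out the arrays that stood apart, the exact permutation of list means, their sign flip by replicate number and leaving Fmr1 out of the correlation were tests chosen after seeing the data; all other alternatives were set before the data were examined. Fmr1 kept its direction at every probe set under every alternative run, the counts of association differences stayed at 0, and the correlation of association between genotypes stayed between 0.961 and 0.983. Values of single named genes kept direction and side of the threshold in 183 of 184 cases in polyribosomal RNA, 125 of 155 in total RNA, 1693 of 1696 for association in WT, 1720 of 1722 in Fmr1 KO and 151 of 151 for its difference, and none changed direction. The kept direction says little, also for Fmr1. The replicate block, the fit to all arrays and the log2 cut left differences unchanged, as for Maob in total RNA (-0.496). Genes named for one direction in all 6 same-numbered pairs or lysates cannot reverse when a replicate number is left out. The scaling alternatives moved the median of all genes by at most 0.04. Signal near background limits the dim probe sets, and the number of lysates limits small changes.

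The 3 probe sets called between genotypes in polyribosomal RNA became 5 with all 24 arrays in one fit, where Haus7 had an adjusted p = 0.00727, and 1 with 1 probe set per gene, which tests fewer probe sets of Fmr1. The 7 called in total RNA became 4 with the replicate block, with all 24 arrays in one fit, with 1 probe set per gene and with a log2 change of at least 0.5, 3 with a filter of 6, and 2 to 4 without 1 replicate number. With all 24 arrays in one fit, Maob, Fundc2 and Lgals1 each had a limma adjusted p = 0.999993. Lgals1 was also lost with quantile normalization (adjusted p = 0.0789), median centring (0.0754) and the intensity trend with a robust prior (0.107). Probe sets called in WT between polyribosomal and total RNA became 6489 with 1 probe set per gene and 6710 with a log2 change of at least 0.5, of which 48.5% were higher against 55.4% of all called. In Fmr1 KO they became 6603 and 6729. The changes with 1 probe set per gene and with the log2 cut follow from fewer tests or a stricter rule. For the block, the filter, the fit to 24 arrays, the scaling, the trend and leaving out a replicate number, the cause was not tested.

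With an estimated correlation 0 lists were called in any comparison. In polyribosomal RNA the 6 lists became 0 with fry and 0 with the exact permutation, and 1 to 11 without 1 replicate number. In total RNA the 0 lists became 1 with fry, 6 with no filter on dim probe sets, 3 with the mean of the probe sets of a gene, and 0 to 5 without 1 replicate number. In WT the 6 lists became 17 with fry and 0 with the exact permutation, and in Fmr1 KO the 5 became 21, 22 and, with no filter, 9. For the difference in association the 3 lists became 0 with fry, 0 with the exact permutation, 6 with the mean of the probe sets and 1 to 8 without 1 replicate number. The exact p cannot go below 0.0313 with 6 lysates, and it reached this value in 17 of 28 lists in WT and 22 of 28 in Fmr1 KO. Adjusted, this gave 0.0515 and 0.0398, so the 0 and 22 lists do not show a loss in WT or a gain in Fmr1 KO. With the sign flip of list means by replicate number, which has the same lowest p, 0 lists were called in polyribosomal RNA, total RNA and association, which says little, since a call would need most lists at that value. Lower in Fmr1 KO in 6 of 6 pairs were the postsynaptic density, immediate early genes and the FMRP family and partners in polyribosomal RNA (adjusted p = 0.302 each) and the last also in total RNA, where excitatory neuron markers were higher in 6 of 6 (adjusted p = 0.438 each). Chance gives about 0.9 such lists in each comparison.

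The FMRP-bound list in total RNA, never past the threshold, changed direction with the exact permutation (adjusted p = 0.974), with the sign flip (0.972) and without replicate 1, 2 or 6 (0.902, 0.802 and 0.728, in a range of 0.0852 to 0.992). The correlation of genotype differences between RNA kinds lay between 0.266, without replicate 4, and 0.416, and at 0.321 without Fmr1. The cause of these changes was not tested, but fry tests a list alone and not against other genes.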

Other observations

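The tests of this part were set before the result was seen. A hypothesis was that differences in cell composition between cortices were shared by the WT and Fmr1 KO lysates of one number, as littermates or samples prepared together may share them. Marker means in total RNA were compared between WT and Fmr1 KO over the 6 numbers for 3 lists, with exact permutation p values adjusted over the 3 lists. For oligodendrocyte lineage markers Pearson's r was 0.787 (exact permutation p = 0.103, adjusted p = 0.154) and Spearman's rho 0.943 (exact permutation p = 0.0167, adjusted p = 0.050). For radial glia and progenitor genes r was 0.820 (exact permutation p = 0.0458, adjusted p = 0.138) and rho 0.886 (exact permutation p = 0.0333, adjusted p = 0.050). For cell cycle genes r was 0.656 (exact permutation p = 0.182, adjusted p = 0.182) and rho 0.257 (exact permutation p = 0.658, adjusted p = 0.658). Without the 2 numbers farthest from the median r was 0.526, 0.856 and 0.432 in this order. None of the 3 passed the threshold, so these tests over 6 numbers do not tell shared differences apart from chance.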
